A study of Mus musculus with 3 samples.

How the data were processed

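Newly made RNA was measured by Bru-seq in the mouse pancreatic cancer cell line NB490, which carried a doxycycline-inducible short hairpin RNA (shRNA) against PDX1. In Bru-seq, cells take up bromouridine for a short time, the labelled RNA is captured with an antibody, and its sequence reads report transcription during the labelling window and not the RNA already stored in the cell. Labelling was with 2 mM bromouridine for 30 min, per the labels' protocols. The 3 libraries were 1 from uninduced cells, 1 from cells kept in doxycycline for 48 h and 1 from cells grown out in doxycycline for more than 3 weeks. With 1 library per condition there was no replicate, so no p-value was computed, and every difference compares those libraries and has no replicate check.

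The submitters' processing notes name CASAVA 1.8.2, Bowtie 0.12.8, TopHat 1.4.1 and bedtools 2.16.2, without their settings. The deposited estimated counts, per the file headers a read count for each whole gene model with introns and exons together, were not all whole numbers: between 47.3% and 48.5% of the counts above 0 were whole reads, within 0.01 of a read. The rest fell on multiples of 1/52 of a read, within 0.1 of such a step, for 99.99% to 100% of values below 5000 reads. The deposited RPKM values, per the file headers reads scaled by the length of the gene model and by the library total, were used as the main measure. A further deposited column, of another unit with reads per base, is the authors' and was not needed for the comparisons. Whole gene models were used by the authors, so a long gene can gather intron reads over its whole span. A difference in how far transcription had travelled can then enter its value. For some models, several of which overlap another on the same strand, the deposited length was far shorter than the span. It was 1765 of 7880 bp for Ankrd1 and 3917 of 417630 bp for Glis3. Lengths below are those deposited, so such long genes count as short. The submitters' processing notes name the human build hg19, whereas the models carry mouse gene symbols. Models on chromosome 1 reach position 197002909, past the last gene of mouse build GRCm38, and only 313 of 20046 models with a symbol in the GRCm38 gene table start within 10 bp of its start. The coordinates therefore belong to neither build and are given as in the files, with the build not given in the sources used here. The GRCm38.p6 table was used to match gene names and for this check of the build. Strand was taken from the data: nested models on the opposite strand of a host gene had a median density ratio to it of 0.000323 (32 models), against 1.19 for those on the same strand (12 models).

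The read total behind the RPKM values was 51006774 in the uninduced, 48418864 in the 48 h and 41632296 in the grown-out library. Gene models held 79.3%, 78.1% and 79.4% of these reads. Of 22658 models, 138 were left out, namely 133 with a repeated symbol and 17 spanning over 3 Mb, some being both; they held 0.582% to 0.628% of the gene model reads. A gene was measured where its mean RPKM over the 3 libraries was at least 0.5 and its model at least 300 bp long, which 7915 models met. The log2 ratio was taken of RPKM plus a pseudocount of 0.05, which understates changes of low genes. The plain fold is the ratio of RPKM values, with an exact conditional binomial 95% interval from the read counts. A gene was counted as past 2-fold where its log2 ratio reached that size and the interval excluded no change. Levels carry exact Poisson 95% intervals. With 1 library per condition, these intervals cover counting error only. Some medians in the closing sections carry other ranges, from redrawing genes or counts, as named there. None covers variation between cultures. Reads were not counted by molecular identifiers, so repeat reads of 1 molecule could make the intervals too narrow.

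Gene lists, the measures and the rule for named genes were fixed before the data were examined. The rule takes, for each comparison with the uninduced library, the 10 higher and 10 lower genes past 2-fold whose interval bound nearest to no change lies farthest from it, and 5 each for grown-out against 48 h. Unnamed and small RNA models are left out of it. Pdx1, Cdh1, Vim, Zeb1, Sox9 and Myc were always named, and up to 4 members with the largest ratio in each list. Some genes that the rule names are not reported here. A list's median log2 ratio was placed among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries. The lists covered pancreatic transcription factors, epithelial, mesenchymal, acinar, ductal, endocrine, gastric and mucin, and squamous genes. They also covered S phase, G2 and M phase, p53 target, interferon, stress response, hypoxia and glycolysis, cholesterol synthesis and ribosome biogenesis genes. Further lists held immediate early and ERK, inflammatory, TGF-beta and YAP, and Wnt, Notch and Hedgehog genes, reference, histone and ribosomal protein genes, and fibroblast, immune and endothelial markers. Mitochondrially encoded genes were also listed and are not analysed here. Of the listed symbols, Tff1 and Hmgcs1 had no unique model and were not used here.

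Alternatives were the TMM scaling of edgeR 4.0.16 and the size factors of DESeq2 1.42.0 (R 4.3.3), both on rounded counts, other filters, pseudocounts and fold thresholds, and random lists matched also on length. The remaining steps ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The counting rule was tested on simulated data for 48 h against uninduced over 7915 genes. With counting error only it called 0% of genes changed 1.5-fold, 100% of those changed 2.5-fold, and 0 of 7715 unchanged genes. With an assumed coefficient of variation of 0.2 between cultures it called 28% and 76% of these and 109 unchanged genes, and the 95% interval covered the true fold in 23.5% of changed genes. The same test for grown-out against uninduced gave 100% of 2.5-fold genes with counting error only, and 72% with 107 unchanged genes called under the assumed variation.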

Results

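The study addressed PDX1, a transcription factor of pancreas development, in the start and upkeep of pancreatic ductal adenocarcinoma. NB490 mouse pancreatic cancer cells with an inducible PDX1 shRNA were profiled as 3 Bru-seq libraries: uninduced, after 48 h of doxycycline, and grown out in doxycycline for more than 3 weeks. Each condition had 1 library and no replicate, and cells given doxycycline without this shRNA were not analysed here. Median reads over the 7915 measured genes were 2038, 1896 and 1667 in the uninduced, 48 h and grown-out libraries. The 10 models with most reads held 2.05%, 1.98% and 2.22% of gene model reads.

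Nascent RNA of Pdx1 itself (chromosome 5, 148081707 to 148086725, plus strand) was lower after 48 h and close to the uninduced level in grown-out cells. Its level was 1.59 RPKM in the uninduced library (95% Poisson interval 1.44 to 1.75), 1.05 at 48 h (0.928 to 1.19) and 1.41 in grown-out cells (1.26 to 1.59). The 48 h value was 1.51-fold lower than the uninduced one (1.28 to 1.77), and the grown-out value 1.12-fold lower, with an interval that included no change (0.961 to 1.30). An shRNA acts on finished mRNA, so these values do not measure how far the mRNA or protein was reduced. Vim, a mesenchymal filament gene, had 34.6, 25.2 and 36.4 RPKM in the same order, and Cdh1, which encodes E-cadherin, had 4.81, 4.63 and 5.35 RPKM. Zeb1, a repressor of epithelial genes, had 1.73, 1.77 and 1.47 RPKM. Myc had 7.54, 6.25 and 6.83 RPKM. Sox9, a duct factor, lay under the expression minimum at 0.198, 0.119 and 0.216 RPKM. None of these genes was past 2-fold in any comparison.

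**Figure D1:**
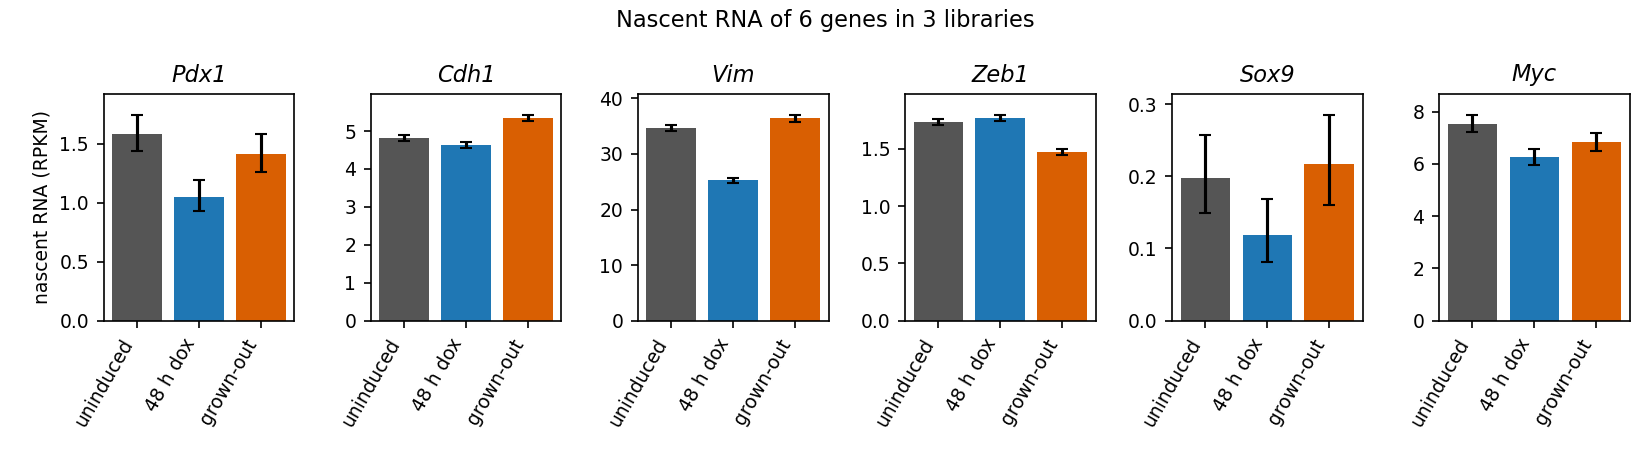
Nascent RNA in RPKM (y axis, from 0, a scale for each gene) of 6 genes in the uninduced, 48 h doxycycline and grown-out libraries, 1 library each; error bars are 95% Poisson intervals for counting error only. Pdx1 was 1.59, 1.05 and 1.41 RPKM.

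The first comparison asked what was transcribed differently 48 h after the shRNA was switched on. Of the measured genes, 59 were past 2-fold, 57 of them lower. Beyond counting error, meaning an interval that excluded no change, 2383 of all 7915 genes were higher and 2372 lower. The list counts below should be read against that background. The most firmly lower genes by counting error included Sepp1, a selenium transport protein, at 4.37-fold lower (3.81 to 5.03), and Txnip, a regulator of glucose uptake, at 3.74-fold lower (3.30 to 4.25). Egr1, an immediate early transcription factor, was 3.50-fold lower (3.15 to 3.89), and the neutrophil chemokine genes Cxcl1 and Cxcl5 were 3.57-fold (3.09 to 4.15) and 2.77-fold (2.32 to 3.31) lower. Spp1, which encodes osteopontin and was among the most transcribed duct genes here, had 98.6 RPKM in uninduced cells and was 2.47-fold lower (2.41 to 2.52). Junb was 2.96-fold, the histone gene Hist2h3c1 2.78-fold, the epithelial transcription factor gene Bnc1 2.70-fold and the aldo-keto reductase gene Akr1b8 2.51-fold lower. The 2 higher genes were Rdm1, a DNA repair gene, at 2.46-fold (2.10 to 2.89), and the unnamed model 2810403D21Rik, which was outside the naming rule and chosen after its values were seen.

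Genes of immediate early and ERK signalling were lower at 48 h as a group. Of 25 measured, 22 were lower beyond counting error, 1 was higher, and 7 were past 2-fold lower, with a median log2 ratio of -0.49 at percentile 0 of random lists. Besides Egr1 and Junb, Jun was 2.49-fold and Dusp6, a feedback inhibitor of ERK signalling, 2.29-fold lower. Cholesterol synthesis genes had a median of -0.63, also at percentile 0, with 18 of 19 lower beyond counting error and 0 higher. Insig1, a sterol sensor partner, was 2.29-fold lower, Lss 1.89-fold, Idi1 1.86-fold and Cyp51 1.77-fold lower. Inflammatory cytokine and NF-kB genes had a median of -0.62, with 9 of 10 lower beyond counting error. Besides Cxcl1 and Cxcl5, Relb was 1.74-fold lower, and Nfkbia, the inhibitor of NF-kB, 1.59-fold lower.

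Genes of pancreatic and epithelial identity were also lower at 48 h. Of 9 measured pancreatic transcription factors, Pdx1 included, 7 were lower beyond counting error and 0 higher. Their median log2 ratio was -0.44, at percentile 0.01. Hes1, a Notch effector, was 1.95-fold lower, Onecut2 1.76-fold and Foxa2 1.54-fold lower, while Gata4 stayed at 1.39 RPKM in both libraries. The lists below share genes and are not independent. Hes1 is also in the Wnt, Notch and Hedgehog list, Onecut2 in the gastric list, and Muc1 and Krt19 in both the epithelial and ductal lists. Epithelial genes had a median of -0.27 at percentile 0.02, with 17 of 20 lower beyond counting error and 1 higher. Muc1 was 1.84-fold, Jup 1.79-fold and Krt19 1.70-fold lower, and the member that was higher, Krt18, by 1.06-fold. All 11 measured ductal genes were lower beyond counting error, with a median of -0.30 at percentile 0.10. The 4 measured gastric and mucin genes had a median of -0.78 at percentile 0, with Anxa10 1.83-fold, Onecut2 1.76-fold and Vsig1 1.73-fold lower. Wnt, Notch and Hedgehog genes had a median of -0.56 at percentile 0, with 6 of 7 lower beyond counting error. That list holds ligands and receptors besides targets, so it does not measure pathway output. Jag1, a Notch ligand gene, had 2.20 RPKM uninduced and 1.23 RPKM at 48 h. TGF-beta and YAP target genes had a median of -0.20 at percentile 0.03. Of these 20 genes, 13 were lower beyond counting error and 4 higher, and those past 2-fold were Id1 at 3.17-fold, Id2 at 2.23-fold and F3 at 2.21-fold lower. Mesenchymal genes had a median of -0.12 at percentile 3.37, inside the middle 95% of random lists, with 9 of 19 lower and 2 higher beyond counting error; Twist2 was 2.19-fold lower. Ribosome biogenesis genes had a median of +0.10 at percentile 99.1, with 10 of 26 higher and 2 lower, but lay inside the random range, at +0.07 for 14 genes, where a mean RPKM of at least 2 was required. Requiring a mean RPKM of at least 2 left 24 genes past 2-fold and a pseudocount of 0.5 left 22, all of them lower.

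The second comparison asked what differed once cells had grown out under doxycycline. Of the measured genes, 69 were past 2-fold, 56 lower and 13 higher. Beyond counting error, 2658 of all 7915 genes were higher and 2331 lower. The largest difference among the named higher genes was Prl2c2, a prolactin family gene (chromosome 13, 13088391 to 13097597, minus strand), at 8.47-fold higher (7.56 to 9.51), from 0.733 to 6.20 RPKM. It belongs to a family of similar genes, so its value is uncertain. Nrn1, which encodes neuritin, was 2.24-fold higher (2.10 to 2.39), and the RNase P RNA gene Rpph1 2.12-fold higher. Tnni2 was 2.40-fold (1.58 to 3.65) and Mrps26 2.41-fold (1.53 to 3.87) higher, on 72.4 and 59.4 reads. The histone genes Hist1h3g, Hist1h2bj and Hist1h3i were also higher, but on 20.6, 12.6 and 18.6 reads. Klra18 was 2.49-fold higher on 61 reads, and is uncertain because its model overlaps 2 others on the same strand within a gene family. Among lower genes, Egr1 was 6.92-fold lower (5.96 to 8.05), Tm4sf4 5.45-fold (4.66 to 6.40), Ly6e 4.82-fold (3.70 to 6.37) and Btg2, an antiproliferative gene, 4.42-fold lower (3.35 to 5.92). Fn1, which encodes fibronectin, was 3.43-fold lower (3.27 to 3.60). Txnip was 4.06-fold, Sepp1 4.05-fold, the cytochrome gene Cyp1b1 3.95-fold, the apoptosis gene Pawr 3.19-fold and Spp1 3.06-fold lower.

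Cholesterol synthesis and immediate early genes were lower in grown-out cells too. Cholesterol synthesis genes had a median log2 ratio of -0.44 at percentile 0, with 17 of 19 lower beyond counting error and 0 higher. Insig1 was 1.92-fold and Nsdhl 1.91-fold lower. Immediate early and ERK genes had a median of -0.26 at percentile 0, with 18 of 25 lower and 3 higher beyond counting error. Jun was 2.86-fold and Spry1 2.82-fold lower, while the growth factor genes Ereg and Areg were 1.44-fold and 1.39-fold higher. Pancreatic transcription factors and epithelial genes lay inside the middle 95% of random lists, with medians of -0.04 and -0.01, signs that scaling could turn. Foxa1 was 1.93-fold and Hes1 1.58-fold lower, whereas Foxa2 had 1.37 RPKM against 1.36 in uninduced cells. Gastric and mucin genes had a median of +0.16, with Anxa10 1.89-fold and Vsig1 1.58-fold higher and Onecut2 1.25-fold lower. Ductal genes had a median of -0.18 at percentile 0.82, and inflammatory genes one of -0.22 at percentile 0.30, with Cxcl12 2.45-fold lower. With a mean RPKM of at least 2, the inflammatory list kept 6 genes and lay inside the random range, at -0.16. Wnt, Notch and Hedgehog genes had a median of -0.19, inside the range of random lists.

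Ribosome biogenesis genes were higher in grown-out cells: 22 of 26 were higher beyond counting error and 0 lower, with a median log2 ratio of +0.37 at percentile 100. Bop1 was 1.75-fold, Nop2 1.52-fold, Ncl 1.48-fold and Nop16 1.46-fold higher. Replication-dependent histone genes had a median of +0.45 at percentile 100 (0.46 for 27 on chromosome 13 and 0.17 for 8 elsewhere), with 15 of 35 higher and 2 lower beyond counting error. Mesenchymal genes had a median of -0.23 at percentile 0, with 12 of 19 lower and 5 higher beyond counting error. Besides Fn1, Cald1 was 2.67-fold and Loxl2 2.15-fold lower, while S100a4 was 1.45-fold and Axl 1.27-fold higher. The mesenchymal median turned to +0.20 where a mean RPKM of at least 2 was required. TGF-beta and YAP target genes had a median of -0.10 at percentile 1.56, inside the range once random lists were matched also on length. Ctgf was 2.14-fold lower, and Ankrd1 had 42.6 RPKM against 92.0 uninduced. The Ankrd1 values are scaled by 1765 bp of its 7880 bp span. A pseudocount of 0.5 left 25 genes past 2-fold, and a mean RPKM of at least 2 left 18. Few higher genes stayed under stricter filters: 6 with at least 100 reads, chosen after seeing the data, and 3 with a length of at least 3000 bp.

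**Figure D2:**
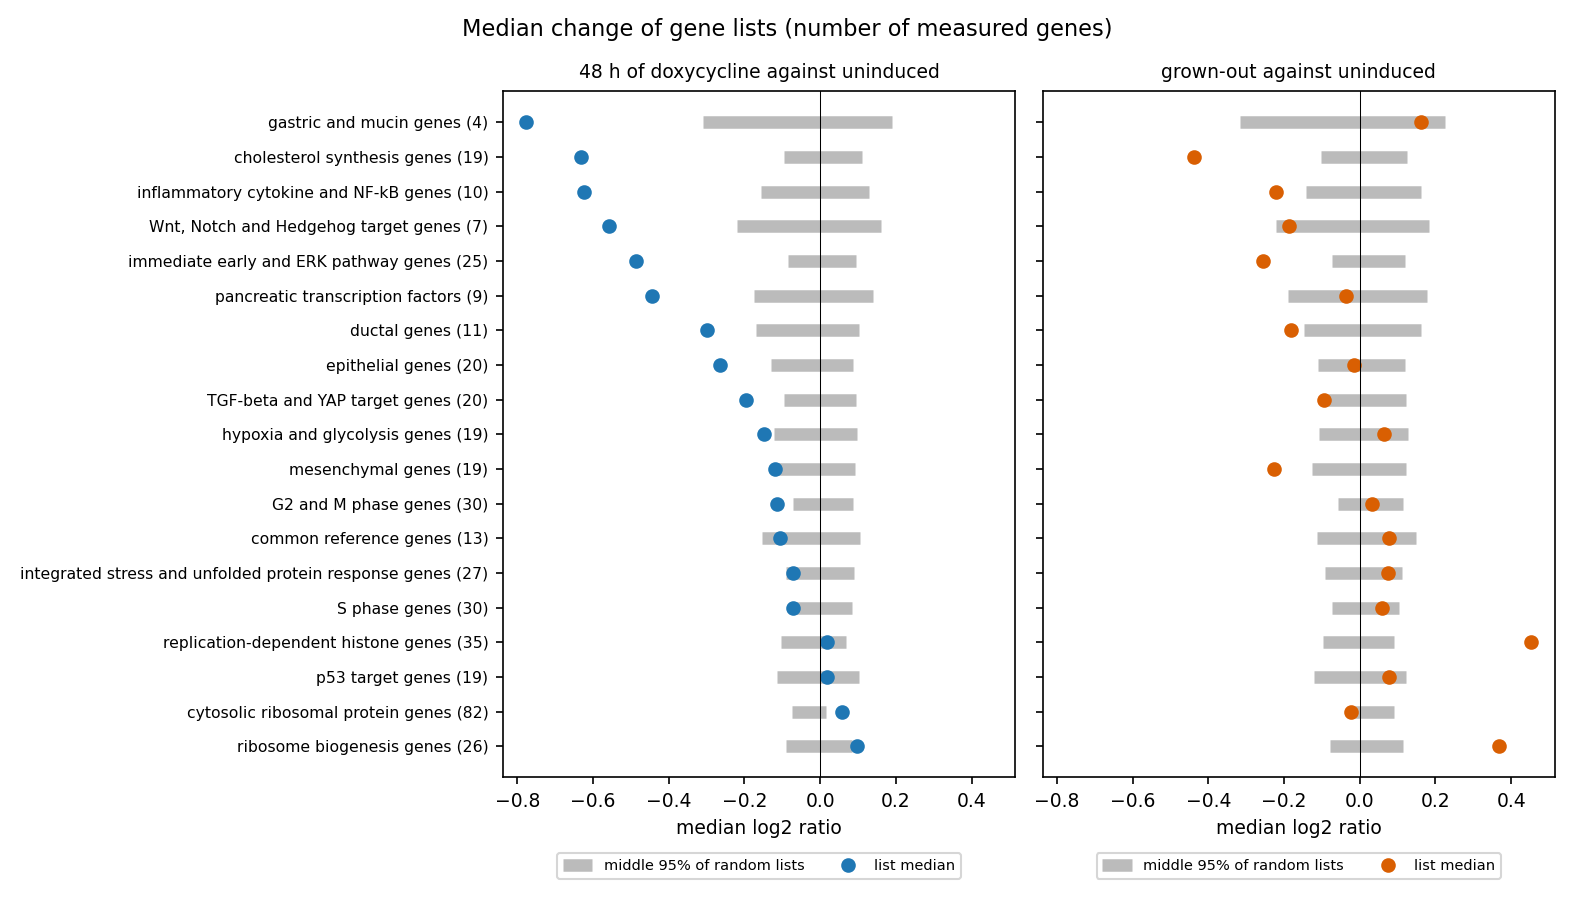
Median log2 ratio (x axis) of 19 gene lists at 48 h of doxycycline (left) and in grown-out cells (right), each against the uninduced library; grey bars are the middle 95% of 10000 random lists matched on expression, and numbers in brackets are measured genes. At 48 h 11 lists lay below the bars and 2 above, and in grown-out cells 7 below and 2 above; the ribosomal protein and epithelial lists on the right lay at -0.02 and -0.01, which turned positive under TMM and DESeq2 scaling.

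Both doxycycline conditions were compared with the same uninduced library. Of the genes past 2-fold, 19 were lower in both, among them Egr1, Txnip, Sepp1, Spp1, Ly6e, Btg2 and Cyp1b1, and 1 was higher in both. Independent lists of these sizes would share 0.403 lower genes and 0.0033 higher ones. In simulations of unchanged libraries, all libraries, the uninduced one included, were redrawn from each gene's level pooled over the libraries. Both simulated comparisons used the same simulated uninduced library. They shared 0.04 lower and 0.08 higher genes with counting error only. With an assumed coefficient of variation of 0.2 between cultures they shared 4.19 and 9.97. That variation also gave 114 genes past 2-fold in each simulated comparison, above the numbers observed. Across genes, which are not independent replicates, the log2 ratios of the 2 comparisons had a Pearson r of 0.361, below the 0.472 and 0.498 of the same 2 simulations. The covariance was 0.0263, against simulated values of 0.00348 and 0.0823. The uninduced library could not be split, so part of the overlap may come from sharing it.

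**Figure D3:**
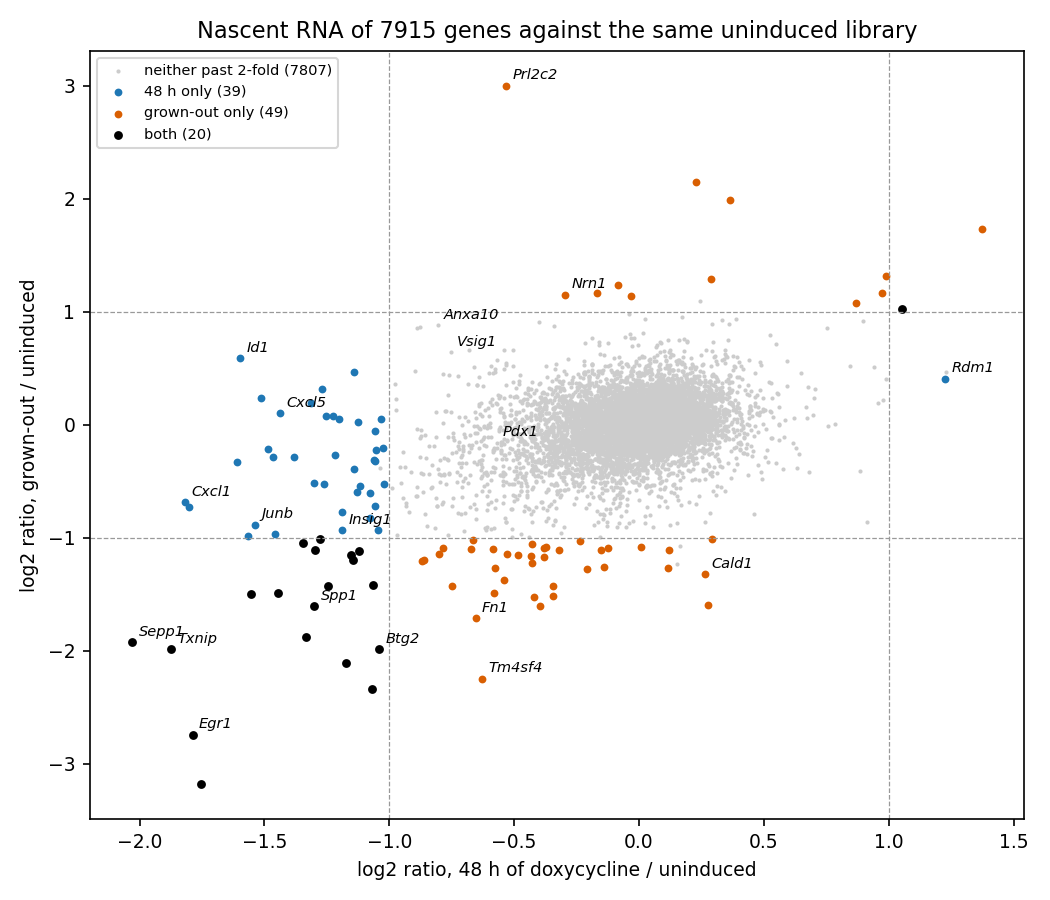
Log2 ratio of each of 7915 measured genes (points) at 48 h of doxycycline (x axis) and in grown-out cells (y axis), both against the same uninduced library; colours mark genes past 2-fold in either, both or neither comparison and dashed lines mark 2-fold. The 20 genes past 2-fold in both lie at the lower left, except 1 at the upper right.

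The grown-out library was also set against the 48 h library, to compare long with short induction. Both libraries already served in the comparisons above. A list low at 48 h therefore tends to come out high here, which is not separate evidence of a change. Of the measured genes, 81 were past 2-fold, 56 higher and 25 lower in grown-out cells. Beyond counting error, 2818 of all 7915 genes were higher and 2530 lower. Prl2c2 was 12.6-fold higher, at 6.20 against 0.491 RPKM, with the uncertainty of its gene family. Id1 and Id2, inhibitors of basic helix-loop-helix factors, were 4.80-fold (3.35 to 7.04) and 3.09-fold (2.70 to 3.54) higher, Anxa10 3.47-fold (3.27 to 3.69) and Bnc1 3.10-fold (2.78 to 3.47) higher. Mrpl53 was 3.55-fold (2.40 to 5.40), Tm4sf4 3.45-fold (2.93 to 4.08), Cald1 3.22-fold (3.03 to 3.44), Wtip 2.69-fold and Thbs1 2.47-fold lower. Epithelial genes had a median log2 ratio of +0.27 at percentile 99.98, with 17 of 20 higher beyond counting error, and pancreatic transcription factors one of +0.30 at percentile 99.6, with 7 of 9 higher. With a mean RPKM of at least 2 the latter list kept 3 genes and lay inside the random range. Gastric and mucin genes had a median of +0.94, cholesterol synthesis genes +0.23, inflammatory genes +0.35, histone genes +0.59 and ribosome biogenesis genes +0.27, each above the middle 95% of random lists. Ribosomal protein genes were the only list below it, with a median of -0.06 at percentile 0 and 30 of 82 lower and 15 higher beyond counting error. Mesenchymal genes, with a median of -0.11, and immediate early and ERK genes, with +0.11, lay inside it. The mesenchymal median turned positive where a mean RPKM of at least 2 was required. With no minimum RPKM the balance changed, since 58.5% of 248 genes were then lower, against 30.9% of 81.

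Markers of other cell types were low in each library, and their summed reads differed between libraries. In the order uninduced, 48 h and grown-out these were 370, 281 and 179 for endocrine, 377, 290 and 181 for endothelial and 267, 186 and 155 for immune genes. Fibroblast genes had 4043, 3754 and 3740 reads, and acinar genes 76, 71 and 59. From uninduced to grown-out cells the endocrine, endothelial and immune sums fell by more than the read total, and the fibroblast sum by less. The acinar sums were too small to tell. No acinar, endocrine or endothelial gene on the lists reached the expression minimum; the highest were Cela1 at 0.0871 RPKM, Pax6 at 0.229 RPKM and Esam at 0.135 RPKM. Of fibroblast markers only Gsn was measured, at 1.27, 1.20 and 1.53 RPKM in the uninduced, 48 h and grown-out libraries. Of immune markers Cd68 had 0.994, 0.916 and 0.901 RPKM, and Cd14 had 1.42, 0.451 and 0.469 RPKM. The measured interferon-stimulated gene, Ifit2, had 1.12, 0.997 and 0.704 RPKM, and the measured squamous gene, Sprr1a, 2.28, 1.32 and 1.13 RPKM.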

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

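The tests of the offset needed, of variation between cultures, of length against all measured genes, of S phase and of chromosome 13 as a whole were chosen after the result was seen. With 1 library per condition, no difference between the 2 doxycycline conditions below was tested.

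Genes that lay at least 1.5-fold below the uninduced library at 48 h and at least 1.5-fold above it in grown-out cells, or the reverse, were singled out. The grown-out against 48 h log2 ratio was 2.18 for Id1, 1.74 for Id3, 1.69 for Anxa10, 1.39 for Vsig1, 1.34 for Syt8 and 1.74 for the pseudogene model Hist2h3c2-ps. Mrpl53 went the other way, at -1.77. Gene models shorter than the length minimum were not part of the comparisons. Of 218 at or over the expression minimum, 2 were higher past 2-fold at 48 h, Snord69 and Scarna8, and 2 in grown-out cells, Sco2 and Snord12. Only higher ones were looked for, so short models that were lower are not given. Apart from Snord12, these rest on few reads, at most 23.1 in the higher library.

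At 48 h, 57 of 59 genes past 2-fold were lower, and still 95% under TMM and DESeq2 scaling, which moved the libraries by only 0.013 and 0.015 on the log2 scale and so test little. An offset of 0.3 would be needed to bring the lower share to 60%. The median of all genes lay at 0.0029 (95% of redraws of the genes, which are not replicates, -0.0023 to 0.0089). This place of the median argues against a scaling error only if most genes were unchanged. Each library was scaled to its own read total, so a shift shared by all genes would not show. The lower genes were short by the deposited length, with a median of 3901 bp against 21790 bp for all measured genes. Yet a general shift of short genes is argued against. Genes drawn from all measured genes and matched on length to the lower ones had a median log2 ratio of -0.019 (95% of draws -0.10 to 0.058). The lower genes had -1.25. Where a length of at least 3000 bp was required, 33 of 34 genes past 2-fold were lower. The planned draw, at -0.0094 (-0.091 to 0.065), left out genes past 2-fold and excludes nothing. Variation between cultures of 1 condition cannot be told apart from the effect of doxycycline or of the shRNA, since 0 conditions had more than 1 library. The induced PDX1 shRNA stays open as a biological explanation, untested.

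Prl2c2 was 8.47-fold higher in grown-out cells. Reads shared with its paralogs cannot be told apart from its own transcription, because 0 other Prl2c genes had at least 20 reads in both libraries. The 5 other Prl2c models together went from 5 to 35.6 reads, 8.73-fold higher (3.45 to 28.8), while Prl2c2 itself went from 344 to 2378 reads. Growth under the shRNA stays open, untested.

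Replication-dependent histone genes had a median log2 ratio of +0.45 in grown-out cells. Short length did not account for it, as length-matched genes had a median of -0.093 (-0.23 to 0.044). A shift of chromosome 13, which holds 27 of the 35 genes, was too small to be the whole cause, at 0.12 (0.087 to 0.15) for its other genes, yet the 27 histone genes there had a median of 0.46 and the 8 elsewhere 0.17, so an effect of the cluster itself stays open. Reads shared between copies stay open, as the summed reads of all 68 models differed by 0.13 (0.070 to 0.19) on the log2 scale. That sum decides little, because it weighs genes by their reads. Hist2h3c1 on chromosome 3 held 1300 of the 4590 uninduced reads and was 1.22-fold lower in grown-out cells. S phase genes had a median of 0.060 (0.030 to 0.099 from redraws of the counts). That is under the 0.15 written down as the limit for no larger share of cells in S phase. That limit was set aside because a high level in cycling cells hides a modest rise. A larger share of cells in S phase therefore stays open too, and growth under the shRNA is untested.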

How the results depend on the processing

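No paired analysis was possible because each condition had 1 library and all were replicate 1. In the order 48 h against uninduced, grown-out against uninduced and grown-out against 48 h, the 59, 69 and 81 genes past 2-fold became 135, 261 and 248 with no RPKM minimum, 24, 18 and 23 with a mean RPKM of at least 2, and 22, 25 and 24 with a pseudocount of 0.5. A threshold of 1.5-fold gave 289, 317 and 462, one of 3-fold gave 8, 17 and 13, and a length of at least 3000 bp gave 34, 43 and 50. The overlap of 20 genes became 81 at 1.5-fold. These settings admit or remove genes by construction. TMM and DESeq2 scaling kept each of these counts within 1.5 times, the overlap at 19. So did alternatives chosen after seeing the data: 55, 57 and 68 genes with at least 100 reads, 54, 53 and 69 without models overlapping on the same strand, and 59, 69 and 81 with repeated symbols and long spans kept. The grown-out median of ribosomal protein genes turned from -0.02 to 0.0036 (TMM) and 0.018 (DESeq2), and that of mesenchymal genes to 0.20 with a mean RPKM of at least 2, where 4 genes were left; each scaling moves all genes by 1 factor per library. Among lists inside the random range, the grown-out epithelial median turned from -0.01 to 0.014 (TMM), 0.028 (DESeq2) and 0.041 (mean RPKM of at least 2), and that of pancreatic transcription factors from -0.04 to 0.0029 (DESeq2). With a mean RPKM of at least 2, the histone median at 48 h turned to -0.20, and against 48 h the grown-out mesenchymal and p53 medians to 0.45 and -0.0096. With random lists matched also on length, the TGF-beta and YAP and the ribosomal protein lists moved inside the random range in grown-out cells. Depth limits the low histone genes, and intervals leave out variation between cultures.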

Other observations

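The tests of chromosome 13 were chosen after the result was seen; the search for shifted windows was planned.

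G2 and M phase genes had a median log2 ratio of -0.11 at 48 h, at percentile 0.27 of random lists, and +0.03 in grown-out cells, and S phase genes -0.07 and +0.06, both inside the random range. Rrm2, a subunit of ribonucleotide reductase, was 1.52-fold lower at 48 h and had 9.07 RPKM in grown-out cells against 9.23 uninduced. Grown-out against 48 h, S phase genes had a median of +0.17 at percentile 99.7, with stress response genes at +0.17 and hypoxia and glycolysis genes at +0.18, each above the random range. The p53 target list had medians of +0.02 and +0.08, inside the random range, yet 3 of its 19 genes were past 2-fold lower in grown-out cells: Btg2, Trp53inp1 at 3.16-fold and Pmaip1 at 2.36-fold. Stress response genes lay inside the range in both, with medians of -0.07 and +0.07, and Atf3 was 2.32-fold lower in both. Hypoxia and glycolysis genes had medians of -0.15, at percentile 0.99, and +0.06. Histone genes had a median of +0.02 at 48 h, with 5 of 35 past 2-fold lower. That median turned negative where a mean RPKM of at least 2 was required. Ribosomal protein genes had a median of +0.06 at 48 h at percentile 99.99, and reference genes -0.11 and +0.08, inside the range.

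As a hypothesis, a gain of chromosome 13 in some of the grown-out cells may underlie part of the difference on that chromosome. The 338 measured genes of chromosome 13 had a median log2 ratio of +0.13 in grown-out cells and +0.02 at 48 h. Prl2c2 and Nrn1 also lie on it, but their log2 ratios in grown-out cells, 3.00 and 1.15, were far larger than that median. The window of 25 genes around Prl2c2 was shifted by only 0.023. Without histone genes the median of chromosome 13 lay at percentile 100 of random gene sets, which argues against the histone cluster as the cause. That place is not particular to chromosome 13: 15 and 16 also lay at percentile 100, with medians of 0.06 and 0.08, and X at percentile 0. At 48 h chromosome 4 lay at percentile 100 and 3 at percentile 0. Of 12 windows of 25 genes along chromosome 13, 91.7% lay above the median of all genes, against 48.3% of other windows, but that chromosome was picked for its raised median, so this leaves a gain open. The planned search for windows shifted by 0.3 or more left copy number open: the largest shift was 0.38, in a window with 20 histone genes, and the largest without histones 0.27. DNA was not analysed here.

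Genes of chromosome X had a median log2 ratio of -0.11 in grown-out cells, a shift about as large as that of chromosome 13. The Y-linked genes Ddx3y and Eif2s3y were 1.99-fold and 1.89-fold lower there than in the uninduced library.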
